A study of Bombyx mori with 12 samples.

How the data were processed

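Gene expression was measured in larvae of the silkworm Bombyx mori on 12 Agilent arrays with 2 colours, each comparing RNA of parasitized larvae with RNA of control larvae of the same tissue. The arrays form 6 dye-swap pairs. In each pair, 1 array carried parasitized RNA in Cy3 and the other carried it in Cy5. Hemocytes were measured after parasitization by 3 species of tachinid fly, whose larvae develop inside the host: Drino inconspicuoides (1 pair), Exorista japonica (1 pair) and Pales pavida (2 pairs). Fat body and silk gland were measured after Pales alone, with 1 pair each. Per the labels' protocols, larvae received 3 eggs at day 0 of instar 5, were kept at 25 °C and were dissected after 5 days. Drino and Exorista laid on the host, whereas Pales eggs were placed on the diet. For each dye, 500 ng of total RNA was labelled. The protocol text names hemocytes and fat body as the tissues collected, and the titles add silk gland.

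The deposited scanner files hold spot intensity per dye. Per the submitters' processing notes, they were made with Agilent Feature Extraction 9.1, and per the file headers the arrays of slide 3 were read with a later release. Per the file headers, the scanner software also gave background-subtracted and dye-normalized intensity and a log10 ratio of Cy5 over Cy3. The deposited series table held these log10 ratios with the sign turned on the dye-swap arrays to parasitized over control, within 0.005 of the scanner files, and each of its columns had a median of 0. Its scale and direction were therefore settled. Between 21 and 45.2% of its ratios per array were exactly 0, so a median of 0 does not show that the ratios were centred. The other deposited columns used, the outlier, saturation and background flags, are yes or no marks of the scanner software per the file headers.

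Median spot intensity and median local background were read with limma 3.58.1 in R 4.3.3. The mean spot intensity had been chosen before the data were examined, but the arrays of slide 3 do not carry it, so the median was used on all 12 arrays. The mean was tried as an alternative on the 8 arrays that have it. Background was corrected by normexp with an offset of 50, which draws the ratios of dim probes towards 0, and each array was normalized by loess with its 1417 control spots at weight 0. Control spots and spots marked as outliers (9 to 172 per array) were left out. Saturated spots, at most 14 per channel, were kept. Every ratio was turned to parasitized over control on the log2 scale, and the 2 arrays of a pair were averaged to 1 replicate, because the labels name only a dye swap within a pair. A probe entered a fit if it was well above background in the same RNA on both arrays of at least 1 pair. Between 32.3 and 64.6% of probes were above background per channel. The number of arrays limits the precision.

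The array holds 43803 probes of 60 bases for 34631 contigs, named only by a contig number. None of the contig numbers (0 of 34631) matched the gene table used here, so no gene is named. The 25 lists of immune, tissue and metabolic genes fixed before the data were examined could not be matched to probes and were not tested. The rule for named genes accordingly fell back to at most 2 probe IDs each way per comparison: the largest rise or fall among probes past the threshold that moved the same way on both arrays, with the brightest probe standing for its sequence unit. A sequence unit joins the probes of 1 contig and probes that match over at least 45 bases at 90% identity (blastn 2.17.0, networkx 3.6.1), giving 30571 units.

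Tests were moderated linear models in limma (lmFit and eBayes) with Benjamini-Hochberg adjusted p under 0.05. The mean under Pales in hemocytes and the differences of Drino and of Exorista from Pales came from a model of the 4 hemocyte pairs with a mean per fly. A common mean was fitted to the same 4 pairs. The differences of fat body and of silk gland from hemocytes came from the 4 Pales pairs. With a mean per group, the spread rests on the 2 Pales hemocyte pairs and has 1 residual degree of freedom, so each lone pair is assumed to vary like them. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these pairs, which may be technical. Lone pairs were described without a test: a probe was counted where its mean log2 ratio was at least 1 either way and at least 0.5 the same way on both arrays. For probes not well above background in 1 of the 2 RNAs, a lower bound of the fold was taken from normalized single-channel signals (loess, then Aquantile), with the dim side set to the higher of its own signal and the lowest signal above background on that array.

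The models were tested on simulated pairs with 200 changed probes, under 3 assumptions on the spread that were tried in turn, all of which are given because the outcome depends on them. With the spread drawn from the fitted prior, changes of 2 on the log2 scale were recovered for 100% of probes in Pales hemocytes, 94% over all hemocytes, 84% for Drino minus Pales, 92% for Exorista minus Pales, 80% for fat body minus hemocytes and 84% for silk gland minus hemocytes, and 3.6 to 12.8% of calls were false. With each probe's moderated spread, 98 to 100% were recovered, but 30.6% of calls for Pales hemocytes and 18.1 to 26.3% of calls for the 4 differences were false, against 3.4% over all hemocytes. With each probe's own residual spread, 98% were recovered over all hemocytes, with 8.7% of calls false, 0% for Pales hemocytes and 0% for the differences, where changes of 4 were not recovered either. The nominal error rate is therefore not assured for the models with 1 residual degree of freedom.

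After the data were examined, and because gene lists could not be used, 3 sets of tissue-enriched units were defined from single-channel control signals: at least 8-fold brighter in silk gland, or in fat body, than in the other of these and in the control of Pales hemocyte pair 2 (465 and 362 units), or in all 4 hemocyte controls than in fat body and silk gland (166 units). Definitions from the parasitized signals, from the mean of both signals and at 4-fold were added as alternatives, since a set chosen on 1 RNA of a pair is biased in that pair. The sets were tested with camera (correlation 0.01, and estimated) and fry, and in lone pairs by the percentile of the set's median among 10000 random lists matched on mean signal. Alternatives fixed before the data were examined covered background, normalization, filter, the deposited ratios, arrays kept apart with a dye term, samples in the fit, the variance prior and each pair left out. Mean spot signal, slide as a fixed block in the common test of hemocytes, 1 probe per sequence unit and removal of units enriched in other tissues were added after the data were examined.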

Results

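Expression in hemocytes, fat body and silk gland of silkworm larvae was compared between parasitized and control animals, 5 days after 3 eggs of a tachinid fly were received. Hemocytes, the circulating blood cells, were measured under Drino inconspicuoides (1 dye-swap pair), Exorista japonica (1 pair) and Pales pavida (2 pairs). Fat body, the insect's main metabolic organ, and silk gland, which makes the silk proteins, were measured under Pales with 1 pair each. All ratios are log2 of parasitized over control, and a value of a pair is the mean of its 2 arrays, with the SD of those arrays, which covers technical spread only. Between 16433 probes in silk gland and 26917 in Drino hemocytes were measured per pair. Probes are named by contig number and position, since no gene names could be matched.

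Under Drino, the lowest hemocyte ratios were those of some transcripts that are abundant in silk gland. Of 332 silk gland-enriched units measured, 60 were at least 2-fold lower and 2 were higher. The set had a median of -0.25 (percentile 0 among 10000 random lists, rounded) and a 10th percentile of -1.62. The random lists take units as independent, so percentiles among them are descriptions, here and below. Probe Ka00800_546 (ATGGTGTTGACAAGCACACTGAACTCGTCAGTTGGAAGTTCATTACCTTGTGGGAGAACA) was lower by a factor of 38.2, at -5.26 ± 0.07 (SD, 2 arrays of 1 pair), and Ka00768_718 (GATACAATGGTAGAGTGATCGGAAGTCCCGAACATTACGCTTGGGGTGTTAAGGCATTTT) was at -5.12 ± 0.36. Both belong to the silk gland-enriched set. Among higher probes, Ka21008_71 (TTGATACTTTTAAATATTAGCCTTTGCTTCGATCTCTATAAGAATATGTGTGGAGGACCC) had a measured ratio of 3.77, which is not exact, since the control signal was above background on 1 of 2 arrays. Ka26936_626 (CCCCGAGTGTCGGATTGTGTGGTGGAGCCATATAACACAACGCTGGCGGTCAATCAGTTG) was at least 7-fold higher, its control signal not being well above background. Fat body-enriched units had a median of -0.07 (percentile 16.3), with 9 of 168 lower and 1 higher, and hemocyte-enriched units one of -0.11 (percentile 3.7; -0.36 with median centring), with 8 of 164 lower and 3 higher. In all, 460 probes were higher and 278 lower by the rule of size, or 223 and 191 sequence units. The 2 higher probes are dim in the control and stood at 6.54 and 6.73 by the scanner software's signals, without the offset that draws dim ratios towards 0. There is no replicate check for this pair, and 62.3% of the counted probes were higher with loess against 28.9% with median centring.

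Hemocytes under Exorista showed a similar picture. Silk gland-enriched units had a median of -0.21 (percentile 0, rounded), and 49 of 308 were at least 2-fold lower while 3 were higher. Ka00768_718 was at -5.10 ± 0.36 and Ka00800_546 at -5.04 ± 0.03. The highest probes were Ka13926_454 (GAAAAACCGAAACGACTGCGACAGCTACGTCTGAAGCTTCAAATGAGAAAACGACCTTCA), at 3.31 ± 0.15, and Ka12284_288 (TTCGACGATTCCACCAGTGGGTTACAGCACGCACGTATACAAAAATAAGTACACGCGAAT), at 3.24 ± 0.21, which stood at 2.81 and 2.70 under Drino. Fat body-enriched units had a median of -0.10 (percentile 0.1), with 7 of 141 lower and 2 higher. Hemocyte-enriched units had one of 0.03 (percentile 91.6), which was -0.27 with median centring, with 5 of 166 lower and 5 higher. By the rule of size 425 probes were higher and 162 lower, or 190 and 110 sequence units. No replicate check exists here either, and the share of higher probes was 72.4% with loess, 61.7% with the scanner software's signals and 37.6% with median centring.

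The Drino and Exorista lists overlapped. Of 16243 units measured in both pairs, 64 were at least 2-fold lower in both, where independent lists of 186 and 104 units would share 1.2. Silk gland-enriched were 41 of these. The median of the 64 units was -0.81 in Pales pair 1 and -0.11 in Pales pair 2. Higher in both were 79 units, where lists of 183 and 165 would share 1.9, and 3 units were counted in opposite directions. Across 14735 probes above background in all 6 pairs and without outlier spots in these 2, the ratios had a Pearson r of 0.489 and a Spearman rho of 0.242. Probes are not independent replicates. The control signals of Drino, Exorista and Pales pair 1 differed by SDs of 0.139 (Drino and Pales pair 1), 0.224 (Drino and Exorista) and 0.252 (Exorista and Pales pair 1), against 0.156 to 0.165 between dyes within these pairs. From those of Pales pair 2 they differed by 0.334 to 0.387. The SDs between pairs compare means of 2 arrays, whereas those between dyes compare single arrays in opposite dyes. These measures are unlike and do not show that the controls were the same. The labels do not say that 1 control RNA was used. If it was, unchanged pairs would correlate at 0.499 in simulation, where control and parasitized RNA were given equal spread. The simulated covariance was 0.02, against an observed covariance of 0.0666 over 15472 units. Part of the overlap and of the correlation may then come from a shared control.

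**Figure D1:**
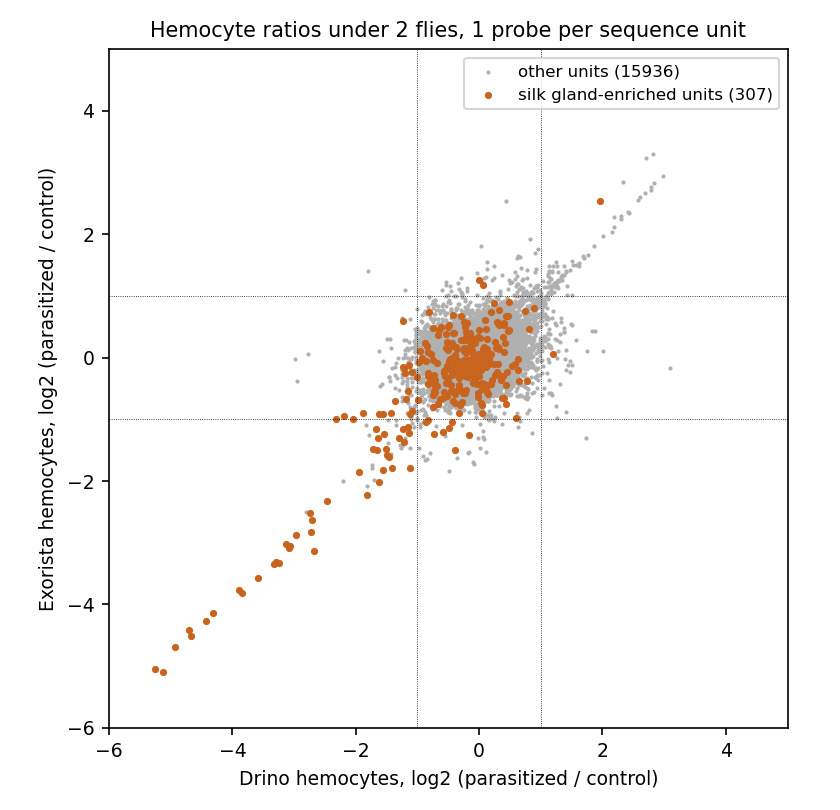
Each point is a sequence unit measured in the Drino pair (x axis) and the Exorista pair (y axis), as log2 of parasitized over control in hemocytes, with dotted lines at -1 and 1. The 307 silk gland-enriched units, in orange, form most of the lower arm, which reaches Ka00800_546 at -5.26 and -5.04.

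Hemocytes under Pales differed from control in fewer probes, and the ratios of the 2 pairs correlated inversely. By the rule of size, 42 probes were higher and 83 lower in pair 1, and 9 higher and 33 lower in pair 2. Silk gland-enriched units had medians of -0.02 and -0.01 (percentiles 5.7 and 5.9), fat body-enriched units of -0.03 and -0.03 (3.4 and 0.9), and hemocyte-enriched units of 0.10 and -0.10 (100 and 0). With median centring the hemocyte-enriched medians were 0.01 and -0.27. No probe passed the threshold for the mean of the 2 pairs with limma, out of 27216 tested, and 306 had an unadjusted p under 0.05 where 1361 are expected by chance. With the scanner software's signals 56 passed, with the deposited ratios 51 and with arrays kept apart 56. Across 14751 probes, the 2 pairs had a Pearson r of -0.27. The 2 arrays within pair 2 correlated at 0.338, against 0.6 in pair 1, 0.814 for Exorista and 0.865 for Drino. The signals labelled parasitized in pair 2 differed from the other hemocyte controls by SDs of 0.348 to 0.402, and those labelled control by 0.334 to 0.387.

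Over all 4 hemocyte pairs, no common response passed the test. With limma 0 of 27216 probes passed, the smallest adjusted p being 0.231. An unadjusted p under 0.05 was found for 2041 where 1361 are expected by chance, but this excess depended on single pairs. The number was 877 without Drino, 432 without Exorista, 2027 without Pales pair 1 and 3075 without Pales pair 2. It ranged from 154 with a robust prior with a trend to 6074 with all 6 pairs in the fit. The fit of all 6 pairs gave each group its own mean. Its spread rested on the 2 Pales hemocyte pairs and, unlike that of the common mean, left out differences between flies. In the set test with a preset correlation, silk gland-enriched units were lower (camera, adjusted p = 7.24e-06; 343 units), and so were fat body-enriched units (adjusted p = 0.000375; 179 units). Neither call held with an estimated correlation, where the adjusted p was 0.309 for both. Hemocyte-enriched units gave an adjusted p of 0.544 by camera. By fry the adjusted p was 0.0473 for fat body-enriched, 0.288 for silk gland-enriched and 0.901 for hemocyte-enriched units. For the mean under Pales alone, camera gave adjusted p of 0.000375 for fat body-enriched units (0.309 with an estimated correlation), 0.154 for silk gland-enriched and 0.902 for hemocyte-enriched units. The sets were defined on these arrays and are not independent evidence. Without Pales pair 2, 10 probes passed in the common test, all lower, and other settings gave between 0 and 88, with 0 for slide as a fixed block.

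Drino differed from Pales in hemocytes in 108 of 27216 probes (limma, adjusted p under 0.05), 97 higher and 11 lower, which belong to 42 sequence units. Ka19218_238 was higher by 3.38 ± 0.14 (SE; adjusted p = 0.0258). Ka21008_71 was also higher (adjusted p = 0.0258), but no exact size can be given, since its control was above background on 1 of 2 arrays. On the lower side, the difference was -4.50 ± 0.20 for Ka00800_546 and -3.70 ± 0.14 for Ka19836_264, another silk gland-enriched probe. Of the 108 probes, 6 were not above background in Pales hemocytes. Exorista differed from Pales in 78 probes of 28 units, 66 higher and 12 lower. Ka16929_1 was higher by 2.89 ± 0.17 and Ka02448_361 by 2.78 ± 0.14 (adjusted p = 0.0315), and both had similar ratios under Drino, at 2.98 and 2.81. Ka00800_546 was lower, at -4.29 ± 0.20, and Ka19836_264 at -3.54 ± 0.14. When units enriched in silk gland or fat body were removed, the lower calls were lost for Drino and nearly all lost for Exorista. With median centring no probe passed in either comparison, and with 1 probe per sequence unit 22 passed for Drino, 14 higher and 8 lower, and 0 for Exorista. A single sequence unit held 21 of the 108 probes for Drino, and 1 unit held 15 of the 78 for Exorista. Within slide 1, which holds Drino and Pales pair 1, 554 probes were at least 2-fold higher and 418 lower under Drino, against 506 and 270 when compared with both Pales pairs. Exorista lies on slide 2 without Pales hemocytes, so slide and fly cannot be told apart there.

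Fat body under Pales had the most probes past the rule of size of any pair. Probe Ka01683_578 (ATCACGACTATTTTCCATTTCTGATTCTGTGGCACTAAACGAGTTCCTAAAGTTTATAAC) was lower by a factor of 479.6, at -8.91 ± 0.49, and Ka07653_427 (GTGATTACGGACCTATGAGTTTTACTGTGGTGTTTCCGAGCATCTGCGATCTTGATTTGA) was at -6.43 ± 0.23. Both are fat body-enriched. Ka04528_815 (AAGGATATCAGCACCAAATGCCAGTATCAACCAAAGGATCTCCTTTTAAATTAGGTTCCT) was higher, at 3.29 ± 0.05, and Ka08144_358 (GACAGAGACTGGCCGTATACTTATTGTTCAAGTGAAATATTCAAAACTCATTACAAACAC) was at least 6-fold higher, its control signal not being well above background. In total 599 probes were higher and 832 lower, 6.13% of those measured, or 415 and 611 sequence units. The share of higher probes was 41.9% with loess, 45.2% with median centring and 47.8% with the scanner software's signals. It was 16.4% among probes with a mean of at least 1.5. Fat body-enriched units spread widely, from a 10th percentile of -2.63 to a 90th of 1.12, but their direction depended on how the set was chosen. Chosen on control signals, 134 of 362 were lower and 68 higher. On the mean of both signals, 84 of 319 were lower and 83 higher, and on parasitized signals 58 of 317 were lower and 102 higher. Silk gland-enriched units had a median of -0.13 (percentile 0, rounded), with 37 of 219 lower and 11 higher, and hemocyte-enriched units one of -0.19 (percentile 0.1), with 6 of 73 lower and 2 higher.

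Compared with hemocytes under Pales, the fat body response differed in 1143 of 28279 probes, 405 higher and 738 lower (limma, adjusted p under 0.05; 861 units). Of these probes, 743 were above background in Pales hemocytes, 314 higher and 429 lower. For the other 400 the hemocyte ratio was not measured, and the difference reflects the fat body ratio alone. Their spread came from hemocyte signals near background, where the offset draws ratios towards 0. Their adjusted p therefore measures no spread of expression between replicates. Ka01683_578 and Ka07653_427, the lowest by difference, are among the 400, with fat body ratios of -8.91 and -6.43. Ka04173_632 was higher by 3.00 ± 0.35 (SE; adjusted p = 0.0431) and Ka08144_358, whose fat body control was not well above background, had an adjusted p of 0.0165, its size being only a bound. The count fell to 2 with a robust prior with a trend, 89 without a filter and 0 with the deposited ratios, and 63.1% of calls were higher with median centring against 35.4% with loess. The lone fat body pair lies on slide 2, which holds no Pales hemocytes, so slide and tissue cannot be told apart here.

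In silk gland under Pales, silk gland-enriched units lay near 0, with a median of -0.03 that was 0.21 with median centring. Of 459, 9 were lower and 1 higher. The percentile of 0 (rounded) is biased, since the set was chosen on control signals of this same pair. Chosen on the mean of both signals the median was 0.008, and on parasitized signals 0.02. Single probes did differ. Ka19145_631 (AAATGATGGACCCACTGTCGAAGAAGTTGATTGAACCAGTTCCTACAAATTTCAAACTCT) was at -4.83 ± 0.03, and Ka25222_692 (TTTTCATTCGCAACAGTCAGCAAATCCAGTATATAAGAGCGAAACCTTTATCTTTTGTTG) was at least 24.4-fold lower, its parasitized signal not being well above background. Ka08568_551 (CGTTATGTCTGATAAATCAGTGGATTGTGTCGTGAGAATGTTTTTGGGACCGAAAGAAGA) was at 2.56 ± 0.04 and Ka03450_209 (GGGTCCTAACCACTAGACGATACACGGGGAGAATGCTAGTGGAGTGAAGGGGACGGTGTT) at 1.85 ± 0.26. By the rule of size 43 probes were higher and 108 lower, so that 28.5% were higher, but sequence units numbered 37 and 40. The share of higher probes was 58.7% with median centring and 45.2% with the scanner software's signals. Fat body-enriched units had a median of 0.02 (percentile 24.5), with 0 of 65 past the rule, and hemocyte-enriched units one of -0.04 (percentile 5.8; 0.10 with median centring), with 1 of 55 lower. No probe passed the test against hemocytes under Pales (limma, 28279 probes, smallest adjusted p = 0.623), and 1972 had an unadjusted p under 0.05 where 1414 are expected by chance. The scanner software's signals gave 75, the stricter filter 104 and arrays kept apart 411. Within slide 3, which holds Pales pair 2 and silk gland, 107 probes were at least 2-fold higher and 147 lower in silk gland, against 62 and 69 when compared with both Pales pairs.

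**Figure D2:**
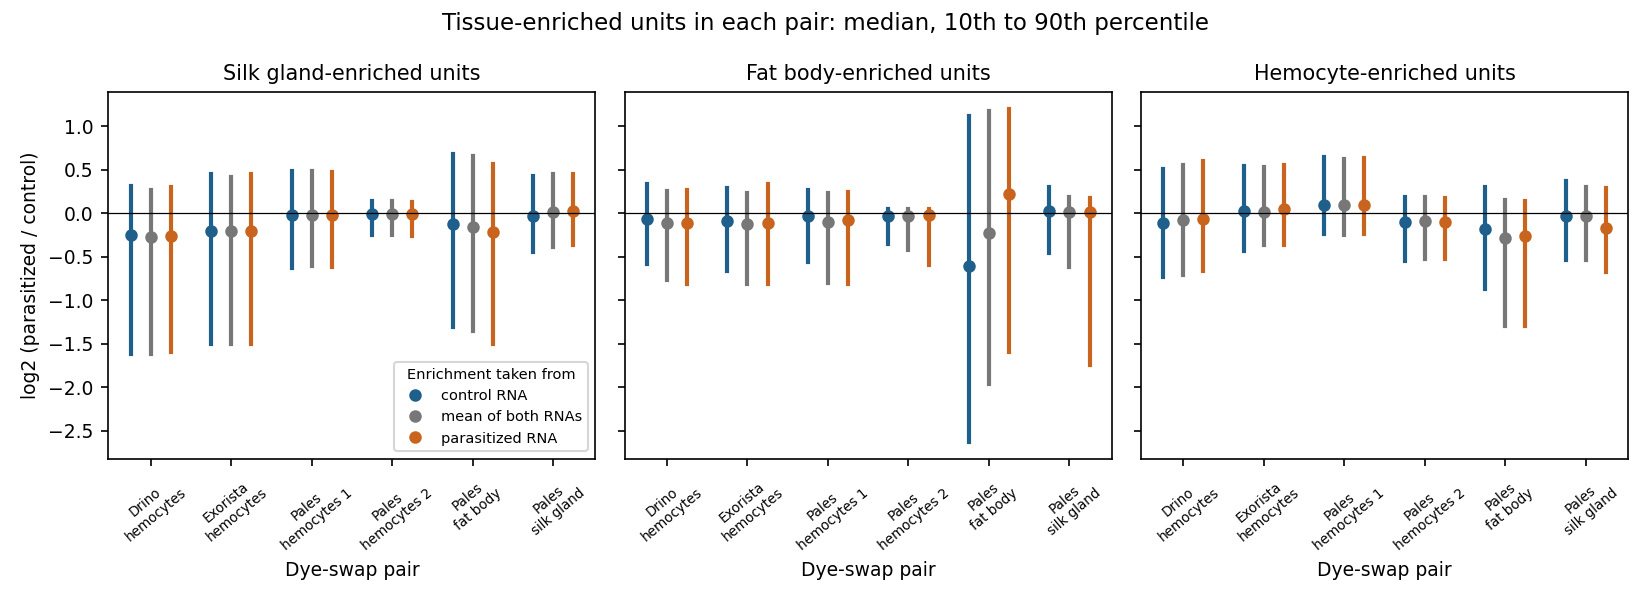
Medians (points) and the 10th to 90th percentile (lines) of log2 parasitized over control for silk gland-, fat body- and hemocyte-enriched units in each of the 6 pairs, with the sets chosen on control, mean or parasitized signals. Silk gland-enriched units reach -1.62 in Drino and -1.50 in Exorista hemocytes under the choice on control signals, while the fat body median in fat body moves from -0.61 to 0.22 with the choice.

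**Figure D3:**
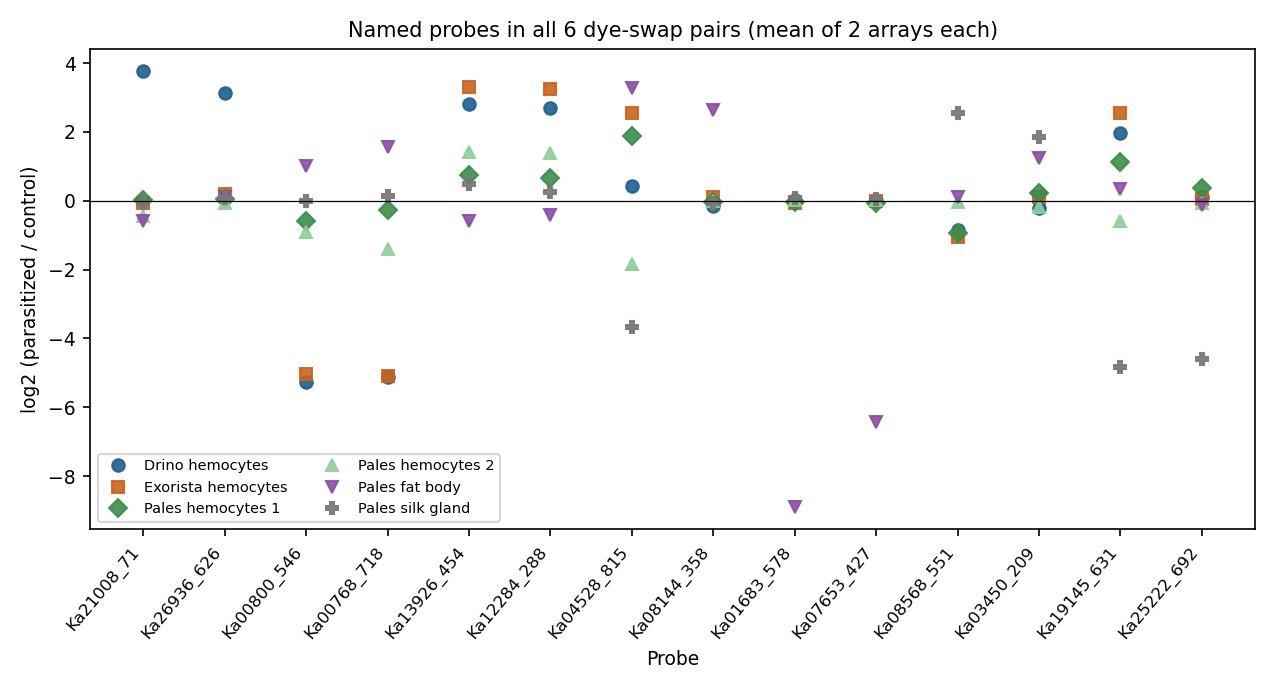
Log2 of parasitized over control (y axis) of the named probes (x axis) in each of the 6 pairs, each point the mean of 2 arrays of 1 pair. Ka04528_815 was at 3.29 in fat body and at -3.66 in silk gland.

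Agreement within and between pairs set the limits of these comparisons. The 2 arrays of a pair had the same sign for 54.5% of probes in Pales hemocyte pair 2 and for 80.3% in Drino hemocytes. In fat body they correlated at 0.908 and in silk gland at 0.648. Different probes of the same contig correlated at 0.876 to 0.919 within a pair. Between pairs, Exorista hemocytes and fat body correlated at 0.322, and Exorista hemocytes and silk gland at -0.301. The first 2 share slide 2 and silk gland lies on slide 3, so slide cannot be set apart in these correlations.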

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

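The tests of silk gland RNA in the control, a shared control alone and together with RNA of other tissues, noise of dim probes, a different control RNA and sign patterns were chosen only after the results had been seen. Among 22 values compared over the 4 hemocyte pairs, 4 had 1 pair far from the others, where chance gives about 1 in 20. Ka19218_238, at 3.09 in Drino, lay apart by a gap of 0.964 of the whole range. Ka21008_71 in Drino, with a measured ratio of 3.77, lay apart by 0.893, and Ka26936_626 in Drino, with one of 3.12, by 0.915, but these 4 values are not exact, since the control was above background on 1 and 0 of 2 arrays. Ka07653_427 in Pales pair 1 also lay apart, by 0.857, but its value was only -0.06 and it was not above background in Pales hemocytes. The named probes had been picked for large changes in these pairs. Past the threshold for a difference between groups were 108 probes of Drino against Pales hemocytes, 78 of Exorista against Pales hemocytes and 1143 of fat body against hemocytes under Pales, of which 400 were not measured in Pales hemocytes. Each rests on 1 pair, with the spread taken from the 2 Pales hemocyte pairs, and with moderated spread 19.8, 23.4 and 26.3% of simulated calls were false. In the common test of the 4 hemocyte pairs, 0 probes passed with the real signs, and the highest other count over the 8 sign patterns was 0, so that 8 of 8 gave as many. With 8 patterns a share under 0.05 cannot be reached.

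Some silk gland-enriched transcripts were at least 2-fold lower in Drino (60 of 332) and Exorista (49 of 308) hemocytes, while others such as Ka19145_631 were higher, at 1.96 and 2.54. The 50 units brightest in silk gland were taken among silk gland-enriched units measured in both the Drino and the Exorista pair. In both pairs 100% of them were above background in control RNA, against 66% (Drino) and 62% (Exorista) in parasitized RNA. Loess normalization is argued against, because with median centring instead, 74% of them in Drino and 62% in Exorista were at least 2-fold lower. These shares are no lower than the 70% and 60% with loess. However, the bound of 70% in both pairs that had been set beforehand was not met in Exorista. The comparison with the loess shares replaced that bound after the result was seen. Silk gland RNA in the control hemocytes stays open: the lower share of 60% lies between the bounds of 50 and 80% set for it. The control signals of these 50 units were at a median of 9.14, 9.11 and 9.15 (log2) in Drino, Exorista and Pales pair 1, with parasitized signals at 6.97, 6.98 and 8.96, and in Pales pair 2 at 7.82 and 7.36. These controls stood at 0.575, 0.566, 0.517 and 0.195% of the silk gland level. A lower expression of these transcripts in hemocytes of parasitized larvae is the biological explanation, which was not tested and cannot be told apart from carried-over RNA here.

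Drino and Exorista ratios correlate. Whether a control RNA shared by slides 1 and 2 is the whole cause stays open. The covariance of 0.0666 (95% bootstrap interval 0.0569 to 0.0767) exceeded those of Drino and of Exorista with Pales pair 1, 0.013 and 0.0274. A control shared alike would make those 2 equal, but their intervals were apart (0.0096 to 0.0164 and 0.0242 to 0.0308). The intervals cover the choice of units and not the spread between pairs, so the comparison does not decide the question. Part of the correlation may still come from a shared control. Without silk gland- and fat body-enriched units r was 0.342, above the bound set beforehand for setting their RNA aside. By itself this does not argue against their RNA, since a shared control can also give a correlation. The simulated 0.499 follows from the equal spread given to control and parasitized RNA, whereas Drino and Pales pair 1 correlated at 0.139. The covariance without the enriched units was 0.0443 (0.0393 to 0.0493), above those with Pales pair 1, 0.0094 and 0.023 (upper bounds 0.0116 and 0.0252). This would argue against both causes together as the whole cause only if the 3 pairs shared 1 control alike. The unequal values of 0.0094 and 0.023 do not bear that out, so this comparison decides nothing either. Differences of Drino from Pales pair 1, in which a shared control would cancel, correlated with Exorista at 0.24 over 15472 units. These include the silk gland- and fat body-enriched units, so this value cannot set apart RNA of those tissues. A response common to both flies stays open as a hypothesis.

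The ratios of the 2 Pales hemocyte pairs correlated inversely, at a Pearson r of -0.27 and a Spearman rho of -0.298 across probes. Over 15472 units r was -0.255, and over the 15090 units left without silk gland- and fat body-enriched units it was -0.312. The inverse correlation therefore does not rest on the enriched units. Transcripts of these tissues outside the enriched sets were not removed, so RNA of these tissues stays open as a cause. Among the 3868 brightest units r was -0.31, which argues against noise of dim probes. A different control RNA in pair 2 stays open: its control differed from the other 3 by SDs of 0.334 to 0.387, against 0.139 to 0.252 among those, and the variance between the Pales pairs, 0.8 times as large in control as in parasitized signals, decides nothing, since slide can widen both. The pairs lie on different slides, read with different software releases, and the labels number them as separate replicates, so slide and sample cannot be told apart.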

How the results depend on the processing

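No paired analysis was possible because the groups compared share at most replicate number 1, which the labels do not tie to common animals. Slide as a random block was not run, since its correlation was not estimable. As a fixed block, chosen after seeing the data, it gave 0 probes over all hemocytes with limma (1356 at an unadjusted p under 0.05). There the spread came only from Drino and Pales pair 1, the 2 pairs on slide 1. It therefore holds a difference between flies and not the spread between replicates. In the other tests slide as a fixed block leaves no residual degree of freedom. The alternatives for gene lists were not run, because no list was matched to probes. Mean spot signal, 1 probe per sequence unit, removal of units enriched in other tissues and the definitions of tissue sets were chosen after seeing the data. Among alternatives fixed before the data were examined, 55 of 109 values stayed within 1.5 times of the main count or within the spread, and 54 moved. Some of the 55 came from leaving out a pair that enters neither the difference nor its residual spread. The cause of the moves was not tested.

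The scanner software's processed signals gave 56 probes for Pales hemocytes, 38 over all hemocytes, 495 for Drino minus Pales, 173 for Exorista minus Pales, 2378 for fat body minus hemocytes and 75 for silk gland minus hemocytes, and by the rule of size 2100 for Drino, 1171 for Exorista, 3124 for fat body and 301 for silk gland. These signals put the median ratio of single arrays between -0.39 and 0.19. The series matrix gave 51, 38, 398, 164, 0 and no change from 0 for these tests, and 2092, 1170, 3120 and 300 by size. Arrays kept apart with a dye term, which treats them as partly independent, gave 56, 44, 5517, 1628, 7460 and 411. Above background in both RNAs on every array, Drino minus Pales gave 518, Exorista minus Pales 250, fat body minus hemocytes 2195 and silk gland minus hemocytes 104. No background subtraction gave 23 over all hemocytes, 219 for Drino minus Pales and 167 for Exorista minus Pales. Median centring gave 0 and 0 for the differences of Drino and Exorista from Pales, 2226 for fat body minus hemocytes and, by size, 335 for Exorista. No filter gave 0, 0 and 89 for these 3 differences. All 6 pairs in the fit gave 88 over all hemocytes, 50 for Drino minus Pales and 0 for Exorista minus Pales. A robust prior with a trend gave 206 for Drino minus Pales and 2 for fat body minus hemocytes.

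By a moderated test in the fit of all 6 pairs, 130 probes passed for Drino, 99 for Exorista, 3160 for fat body and 0 for silk gland. A mean of at least 1.5 left 199, 176, 450 and 41. With 1 probe per sequence unit, 22 passed for Drino minus Pales and 0 for Exorista minus Pales, and the rule of size counted 380 for Drino, 271 for Exorista, 947 for fat body and 72 for silk gland. Without units enriched in other tissues, 1926 passed for fat body minus hemocytes. Leaving out a pair gave 0 to 10 over all hemocytes, the 10 without Pales pair 2, 0 to 0 for Pales hemocytes, 108 to 108 for Drino minus Pales, 129 to 129 for Exorista minus Pales without Drino, 1185 to 1185 for fat body minus hemocytes and 0 to 0 for silk gland minus hemocytes. In the tests with a mean per group, only lone pairs outside the comparison could be left out. Without a Pales hemocyte pair no residual degree of freedom remains. Leaving out the others changes neither the difference nor its residual spread, only the probes tested and the variance prior. These counts are therefore no check on the replicates. A lone pair left by itself was assumed to vary like the others. The split of calls moved too: higher were 61.2% for Drino minus Pales and 58.4% for Exorista minus Pales with scanner signals, against 89.8 and 84.6%.

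The correlation of the Pales hemocyte pairs was -0.193 by the scanner's log ratio and -0.239 without a filter, and that of Drino and Exorista 0.494 and 0.469. Choosing the sets on parasitized signals reversed the fat body median in fat body to 0.219 and the silk gland median in silk gland to 0.02, which follows from choosing on the other RNA of the same pair. On the mean of both signals the silk gland median was 0.008, and with median centring 0.21. In Drino and Exorista the silk gland-enriched median stayed negative under all 5 alternatives, between -0.46 and -0.162 and between -0.35 and -0.129. Signal over background limits what can be seen, most in silk gland, where as few as 32.3% of probes were above it in a channel.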

Other observations

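Ka04528_815 went opposite ways in the tissues and pairs under Pales, at 3.29 in fat body, -3.66 in silk gland, 1.87 in hemocyte pair 1 and -1.83 in hemocyte pair 2, and at 2.55 in Exorista and 0.44 in Drino hemocytes. Ka19145_631, a silk gland-enriched probe at -4.83 in silk gland, stood at 2.54 in Exorista, 1.96 in Drino and 1.12 in Pales pair 1 hemocytes, and at -0.60 in Pales pair 2 hemocytes. Ka13926_454 and Ka12284_288 were above 0 in all 4 hemocyte pairs, at 2.81 and 2.70 in Drino, 3.31 and 3.24 in Exorista, 0.74 and 0.65 in Pales pair 1 and 1.43 and 1.38 in Pales pair 2. Ka00768_718 was at 1.57 in fat body and at 0.13 in silk gland. The 50 fat body-enriched units brightest in fat body were taken among those measured in both the Drino and the Exorista pair. They had medians of -0.42 in Drino, -0.46 in Exorista, -0.46 in Pales pair 1 and -0.03 in Pales pair 2 hemocytes. These probes were looked at together only after their values had been seen, and no test was made of them across tissues.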
